A study of Mus musculus with 2 samples.

How the data were processed

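The deposited files held UMI counts per gene and barcode for 2 libraries, 1 from E10.5 and 1 from E11.5 C57BL/6 embryos, each pooling the dorsal aorta with surrounding tissue and the fetal liver. Per the labels' protocols, cells were dissociated with enzymes and prepared with the version 3.1 kit of the 10x 3' assay. Per the submitters' processing notes, the authors aligned reads to mm10 (GRCm38) and counted UMIs with Cell Ranger 5.0.0. The values were whole numbers, and the lowest total of a barcode was 500 UMIs. Each table listed 31053 genes, of which 31011 identifiers were matched to GENCODE mouse release 21 for positions. The 2 libraries were taken as the 2 groups.

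Barcodes were kept with at least 1000 UMIs, at least 500 genes and at most 10% of UMIs from mitochondrial genes. Of 10996 barcodes at E10.5, 8705 passed (79.2%), and of 12289 at E11.5, 9756 passed (79.4%). Scrublet, run in each library through scanpy 1.11.5, marked 0% of cells at its automatic threshold, so the 8% of cells with the highest score were removed as doublets (696 and 780 cells). This left 8009 and 8976 cells. Globin made up 2.17% and 2.21% of all UMIs.

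Counts were scaled to 10000 per cell and log-transformed. Both libraries were clustered together on 2000 variable genes per library, 40 principal components and 15 neighbours with Leiden at resolution 1.0. Haemoglobin, mitochondrial, Xist and Y-linked genes and 4 lists that were reported on (precursor transcription factors, precursor surface and receptor genes, Notch pathway, and SoxF and arterial regulators) were kept out of the clustering. Vascular and blood clusters were each clustered again. A cluster was named from 28 marker lists when at least 3 markers were at least 3-fold above the other clusters, with at least 20 CPM and a pseudocount of 20 CPM, and when its 10 leading genes did not point to another list. Of 39 clusters, 27 were named. All classes are named by likeness to these markers.

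UMIs were summed over the cells of a class in each library and given as counts per 1000000 (CPM) over all genes other than haemoglobin and mitochondrial genes. Ratios are log2 of E11.5 over E10.5, and were computed in 10 classes or clusters with at least 50 cells in each library. Endothelium and red cells were compared by cluster (2, 12 and 6). The median over the members of a gene list with at least 20 UMIs was set beside 10000 random lists of the same size drawn from the same of 20 expression bins, and its counting interval came from 1000 draws of Poisson counts. In all, 25 lists were described. Shares of cells have exact Clopper-Pearson intervals, CPM values exact Poisson intervals, and ratios exact conditional intervals, all at 95%. A count of 0 was read as an upper limit of 3 counts, and a fold against 0 was computed against that limit in the class and library. Cells were also thinned to 5000 UMIs, leaving out cells with fewer.

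Genes named in a compared class had at least 50 CPM in 1 library, at least 50 UMIs in both together and at least 5% of the level of the highest class. They were ranked by the bound of the interval nearest to 0, with 8 named each way in endothelium and 5 in every other class, and members of the gene lists were named as examples. A few genes that the rule or the lists would name are not reported here. Marker lists, gene lists, the cell filter, this rule and all but 2 of the alternatives were fixed before the data were examined. The naming thresholds, the separate reclustering of vascular and blood cells, the compared clusters of endothelium and the set of main results were chosen after the data had been seen.

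The alternatives were a minimum of 2000 UMIs, at most 5% mitochondrial UMIs, doublets kept, Leiden resolutions of 0.5 and 2.0, each library clustered alone, the reported genes kept in the clustering, CPM over all genes, the median ratio of all genes set to 0, the mean over cells of each cell's CPM, list members with at least 100 UMIs, thinned cells, and the median over cells for globin. Joint reclustering of vascular and blood cells and a count of cells with at least 2 UMIs of Cdh5 and of Runx1 were added later. The intervals were also computed on simulated data, in which 200 of 10919 genes were changed: 95.6% of intervals of unchanged genes and 95.0% of those of changed genes held the true ratio, and 88.5% of those of changed genes lay on the right side of 0. The simulated class totals were drawn from the same Poisson model that the intervals assume, so coverage near 95% followed from the setup. Variation between cells was left out, so the simulation does not test the intervals on these data. No model, p-value or count of changed genes was computed, since cells of 1 library are not replicates. No paired analysis was possible because the 2 libraries share a single replicate number and each stage has 1 library. Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, python-igraph 0.11.9 and matplotlib 3.10.9 were used.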

Results

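Single-cell RNA sequencing was carried out on C57BL/6 mouse embryos at the embryonic (E) days E10.5 and E11.5, with 1 library at each stage. Each library pooled cells of the dorsal aorta with its surrounding tissue and of the fetal liver. Haematopoietic stem cells arise from endothelium of the dorsal aorta and later settle in the liver, and the series concerned their precursors. The E10.5 library held 10996 barcodes with 151474708 UMIs, of which 8009 cells were analysed, with a median of 15470 UMIs and 4154 genes per cell. The E11.5 library held 12289 barcodes with 159619785 UMIs, of which 8976 cells were analysed, with a median of 13134.5 UMIs and 3948 genes per cell. There was no replicate at either stage, so no test between stages was possible, and every 95% interval given here covers counting error only.

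The first comparison asked which cell types made up the tissue at each stage. Erythroid-like cells made up 2.40% of cells at E10.5 (95% CI 2.07 to 2.76, 192 cells) and 11.2% at E11.5 (10.54 to 11.86, 1004 cells), a 4.67-fold higher share (3.99 to 5.47). Megakaryocyte-like cells, the class that releases platelets, went from 0.150% to 1.24% of cells (8.25-fold, 4.54 to 16.5). Macrophage-like cells went from 0.337% to 1.07% (3.17-fold, 2.05 to 5.06) and hepatoblast-like cells, the epithelium of the fetal liver, from 1.25% to 3.22% (2.58-fold, 2.05 to 3.27). Among blood cells alone (254 and 1267), the erythroid-like share was 75.6% and 79.2% (1.05-fold, 0.90 to 1.23), the megakaryocyte-like share 4.72% and 8.76% (1.85-fold, 1.02 to 3.70) and the macrophage-like share 10.6% and 7.58% (0.71-fold, 0.46 to 1.14). Endothelial-like cells of all kinds made up 4.93% at E10.5 and 2.91% at E11.5, a share 1.70-fold lower (1.45 to 1.99), counting vascular subcluster 6 (12 and 38 cells), in which globin was a median of 12.3% of UMIs. Within them, arterial endothelial-like cells accounted for 36.7% of endothelial-like cells at E10.5 and 23.0% at E11.5, and venous or sinusoidal endothelial-like cells for 6.33% and 11.9%. These shares rest on the naming rule, which counted vascular subcluster 2 (114 and 35 cells, median 1936.5 and 2033 UMIs) as endothelial-like without a kind, although Sox17, Hey1 and Gja4 were among its leading genes.

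Outside blood and vessels, somite derivatives were nearly limited to the E10.5 library. Sclerotome-like cells, which form the vertebrae, made up 14.4% of cells at E10.5 (1157 cells) and 0.0557% at E11.5 (5 cells), and dermomyotome or muscle-like cells fell in number from 368 to 28. Notochord or floor plate-like cells numbered 41 at E10.5 and 0 at E11.5, a share at least 15.3-fold lower. That count rests on the naming rule, since unnamed cluster 17 (306 and 0 cells) had Shh and Foxa2 among its leading genes. Mesenchyme-like and mesothelium-like cells were named in the E11.5 library alone (576 and 479 cells). This rests on the naming rule, as the unnamed cluster 18, with 442 cells at E10.5 and 1 at E11.5, shared the leading genes Upk3b, Krt18 and Stk26 with mesothelium-like cluster 29. Because somite derivatives were nearly absent at E11.5, the piece of tissue taken and the stage cannot be separated in these shares. Of 39 clusters, 25 held mostly cells of 1 library, and in such a cluster an effect of the library cannot be separated from a cell type. Cells without a class name made up 46.4% of the E10.5 library and 49.1% of the E11.5 library.

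**Figure D1:**
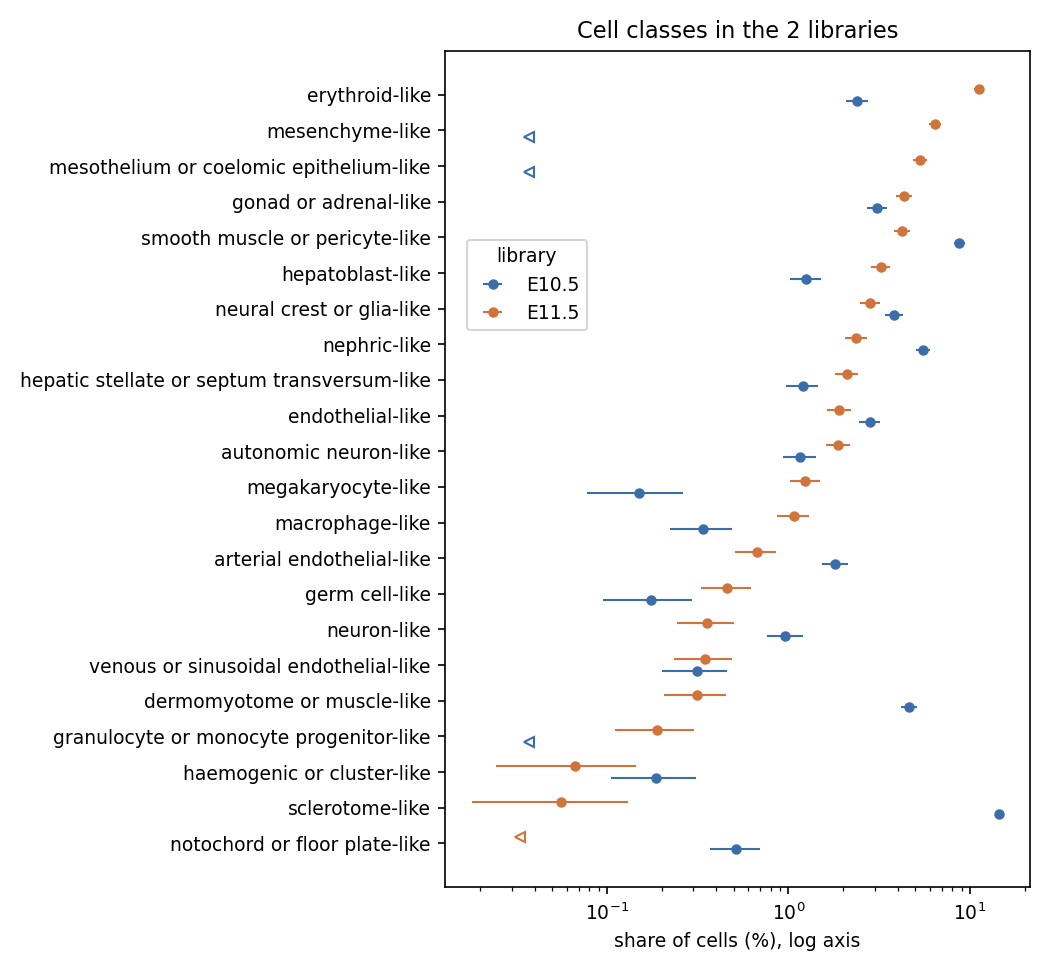
Share of analysed cells in each class (percent, log axis) in the E10.5 and E11.5 libraries, with points for shares, lines for exact 95% intervals and open triangles for the upper limit of 3 counts where no cell was counted. Erythroid-like cells stood at 2.40% and 11.2%, and sclerotome-like cells at 14.4% and 0.0557%.

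Red cells were compared by their globin, since yolk sac-derived primitive red cells carry embryonic globins and liver-derived definitive red cells carry adult ones. Erythroid-like cells fell into 3 clusters. Cluster 6 had similar shares at both stages (2.30% and 2.07% of cells), and Hbb-bh1 and Hbb-y, the embryonic genes, gave 99.4% of its β-like globin UMIs at E10.5 and 93.5% at E11.5. Cluster 31 was counted at E11.5 alone (374 cells, a share at least 111-fold higher), and its β-like globin was 95.6% adult, with 4.37% embryonic (4.31 to 4.43). The median over its cells was lower, at 1.42% embryonic. Cluster 24 went from 8 to 444 cells (49.5-fold, 24.9 to 115), and its β-like globin at E11.5 was 79.9% adult, although β-like globin made up 0.154% of its UMIs against 4.19% in cluster 31. In its 8 cells at E10.5, β-like globin was 91.7% embryonic (84.9 to 96.2, 109 UMIs). β-like globin UMIs were also counted in the other classes examined, where free RNA as their source was not tested. In neural crest or glia-like cells they were 99.03% embryonic at E10.5 and 76.1% at E11.5. The embryonic share at E11.5 was 57.0% in hepatoblast-like and 90.9% in macrophage-like cells.

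Within cluster 6, genes of the red cell membrane had higher levels at E11.5 in all 12 measured members (median log2 ratio 1.14, counting interval 1.04 to 1.27). Among them were the membrane skeleton protein Epb41 (1.97) and the blood group protein Rhd (1.53). Haem synthesis genes had a median of 0.41, inside the range of random lists (-0.51 to 0.48), and it turned to -0.30 when haemoglobin UMIs were counted in the total. S phase genes were lower in 15 of 16 members (median -0.92). G2 and M phase genes were higher in 12 of 15 (0.38, 0.26 to 0.51), inside the range of random lists (-0.50 to 0.41). The red cell membrane median was 0.44 with that total, and 6 of 6 extracellular matrix genes were higher in the same cells (median 2.51), including Col1a2 (5.02), a mesenchymal collagen that red cells are not known to make. Fam174b (5.78), Ackr1, a blood group protein (4.62), Crabp1 (4.43) and Slfn14 (4.02) were the other genes named as higher, and Umps (-2.96), Fos (-2.84), Mrap (-2.70), C1qbp (-2.61) and Mt1 (-2.14) as lower. Crabp1 was also a leading gene of unnamed clusters 15 and 26, which held 536 and 951 cells at E11.5 and 2 and 1 at E10.5.

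The question behind the series, the precursors of haematopoietic stem cells, was addressed in a small group of haemogenic or cluster-like cells, in which Runx1 and the endothelial gene Cdh5 occurred together. It held 15 cells at E10.5 (0.187% of cells, 0.105 to 0.309) and 6 at E11.5 (0.0668%, 0.0245 to 0.145), or 5.91% and 0.474% of blood cells, shares 2.80-fold (1.03 to 8.81) and 12.5-fold lower (4.57 to 39.2). The second fold also reflects blood cells of all kinds, which went from 3.17% to 14.1% of cells. Of 20 precursor transcription factors, 5 stood above all 24 other E10.5 clusters of at least 20 cells. They were Hlf at 97.7 CPM (74.5 to 126), a marker of stem cell identity, Mycn at 254 CPM (216 to 297), Gfi1 at 66.7 CPM (47.9 to 90.5), a repressor of the endothelial programme, Ikzf2 at 226 CPM (190 to 267) and Hoxa9 at 132 CPM (105 to 164). Their levels were 1.97-fold (Hlf), 2.41-fold (Mycn), 6.18-fold (Gfi1), 5.41-fold (Ikzf2) and 2.39-fold (Hoxa9) those of the next highest cluster. That cluster was hepatoblast-like cluster 22 for Hlf (49.5 CPM), unnamed cluster 18 for Mycn and nephric-like cluster 9 for Hoxa9. For Gfi1 and Ikzf2 it was a vascular subcluster. Only 2 of the 24 other clusters were blood clusters. The megakaryocyte-like subclusters and the unnamed blood cluster B3 (8 cells at E10.5) were under that size, so other blood progenitors were not compared. At E11.5, the 6 cells held Hlf at 58.0 CPM (29.0 to 104), Mycn at 68.6 CPM (36.5 to 117), Ikzf2 at 116 CPM and Hoxa9 at 121 CPM, while no UMI of Gfi1 was counted, which allows up to 19.5 CPM.

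At E10.5, an Hlf UMI was found in 12 of the 15 haemogenic-like cells (80.0%, 51.9 to 95.7; median depth 38887 UMIs) and in 5.21% of neural crest or glia-like cells, which are not known to express Hlf (median depth 20357 UMIs). With every cell thinned to 5000 UMIs, the Hlf shares were 26.7% and 1.74%, with 0 and 19 cells left out for lower depth. For Gfi1 the shares were 73.3% and 0.326% before thinning and 26.7% and 0.347% after it. The haemogenic-like cells also held Spi1, a myeloid regulator, at 265 CPM, and the chromatin protein gene Hmga2 at 1170 CPM. Among SoxF and arterial regulators, Sox17 was at 8.14 CPM against 393 CPM in arterial endothelial-like cells, Sox7 at 3.26 against 156 CPM, Sox18 at 53.7 against 301 CPM, Foxc2 at 16.3 against 147 CPM, Foxc1 at 13.02 against 36.9 CPM and Nr2f2 at 17.9 against 11.9 CPM. Of the precursor genes, Mecom was at 92.8 CPM against 402 CPM and Procr at 39.1 CPM against 153 CPM. In GRCm38 coordinates, Hlf (ENSMUSG00000003949) spans chromosome 11 from 90336536 to 90390895, Mycn (ENSMUSG00000037169) chromosome 12 from 12936093 to 12941914, and Gfi1 (ENSMUSG00000029275) chromosome 5 from 107716657 to 107726036. Ikzf2 (ENSMUSG00000025997) spans chromosome 1 from 69531214 to 69687245 and Hoxa9 (ENSMUSG00000038227) chromosome 6 from 52223100 to 52231089.

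The group was fragile. It held 15 and 3 cells at a Leiden resolution of 2.0, and 17 and 0 with each library clustered alone. No cluster earned its name with a minimum of 2000 UMIs, where 19 of the 21 cells lay in an unnamed cluster of 25 cells, with at most 5% mitochondrial UMIs, or with vascular and blood cells clustered again together, where 17 of the 21 cells lay in a granulocyte or monocyte progenitor-like cluster of 73 cells. Cells with at least 2 UMIs of both Cdh5, a cadherin of endothelium, and Runx1, the regulator of blood emergence, numbered 14 at E10.5 and 13 at E11.5 (0.175% and 0.145% of cells), so the lower share at E11.5 did not hold by that count, although 11 of the 14 but only 2 of the 13 lay in the group. At E11.5, 33 cells of an unnamed blood cluster, B3, also held Hlf (42.3 CPM), together with the lymphoid receptors Flt3 (47.5 CPM) and Il7r (39.8 CPM) and the myeloid enzyme Mpo (593 CPM). No UMI of the lymphoid genes Dntt or Rag1 was counted there, which allows up to 3 counts of each. Granulocyte or monocyte progenitor-like cells were named at E11.5 alone (17 cells, 0.189%), a count that rests on the naming rule, since B3 also had Prtn3 and Mpo among its leading genes and held 8 cells at E10.5. The named cells had Mpo at 6253 CPM and Gfi1 at 52.6 CPM.

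**Figure D2:**
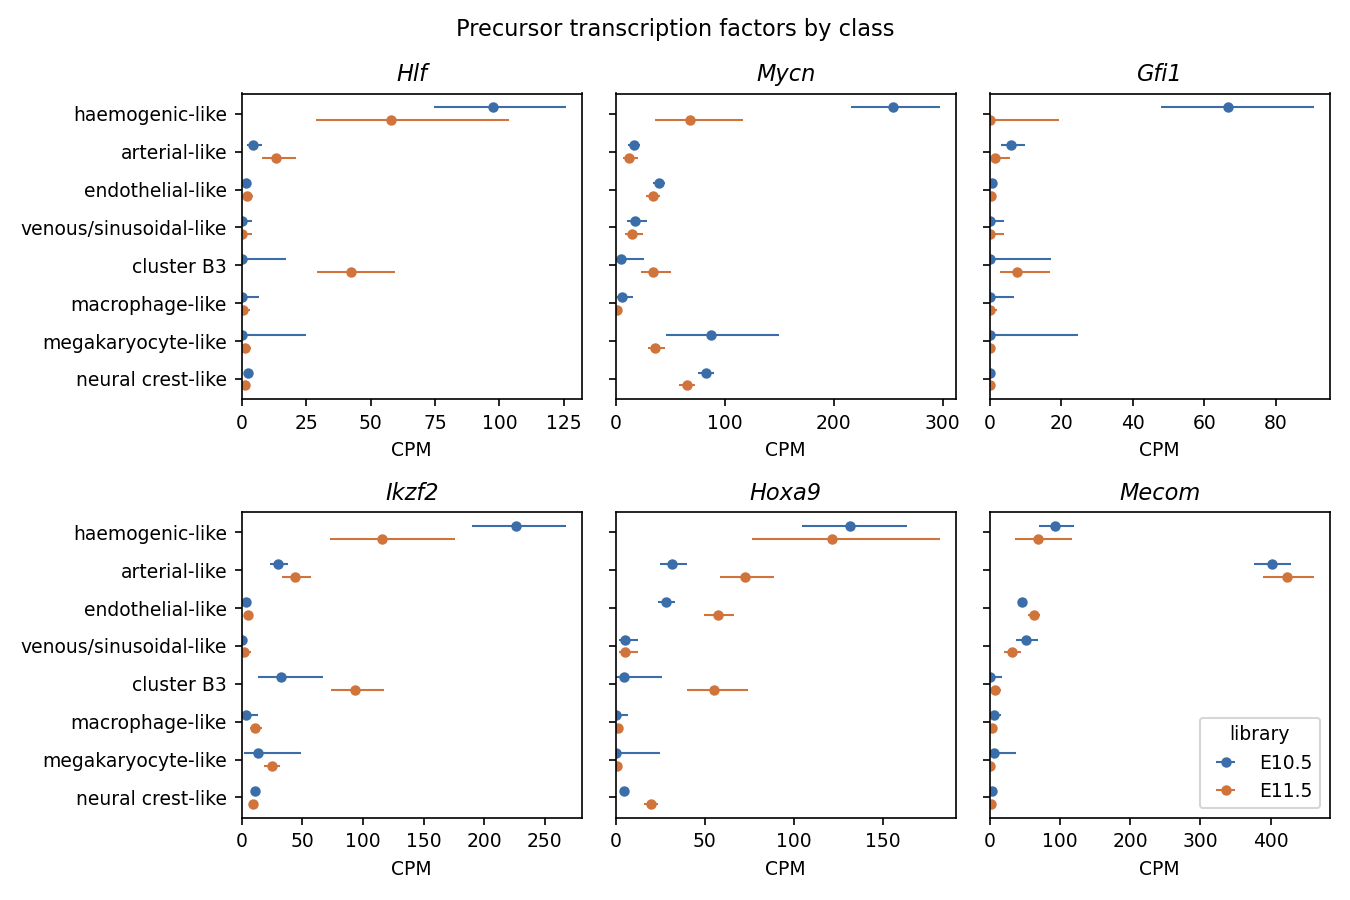
Levels (CPM, with exact 95% counting intervals) of Hlf, Mycn, Gfi1, Ikzf2, Hoxa9 and Mecom in classes of blood and endothelium, the unnamed blood cluster B3 and neural crest-like cells, each point being 1 class in the E10.5 or E11.5 library. At E10.5 the haemogenic-like cells held Hlf at 97.7 CPM, and arterial endothelial-like cells held Mecom at 402 CPM.

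Endothelium was compared between stages in 2 clusters. Cluster 2 held most arterial endothelial-like cells (145 cells at E10.5 and 59 at E11.5). Precursor transcription factors were higher at E11.5 in 15 of 18 measured members (median log2 ratio 0.58, 0.37 to 0.70), a median above all 10000 matched random lists, as a description of these libraries. Among them were Hoxa5 (1.41), Hoxa9 (1.24), Erg, an endothelial and stem cell regulator (1.16), Gata2 (0.79) and Hlf (1.75, 0.54 to 3.04), while Mecom was nearly equal (0.06). Hlf itself stayed low, at 4.24 CPM and 13.3 CPM in arterial endothelial-like cells, with a UMI in 4.14% and 21.7% of cells (median depth 12886 and 16149.5 UMIs). In neural crest or glia-like cells the Hlf shares were 5.21% and 1.98% (20357 and 21750 UMIs), so the E10.5 arterial share was at background. Thinned to 5000 UMIs, the Hlf shares were 0.730% and 8.62% in arterial endothelial-like cells, with 8 and 2 cells left out, and 1.74% and 0% in neural crest or glia-like cells, with 19 and 25 left out. SoxF and arterial regulators had a median of 0.39 with 5 of 6 members higher, including Nr2f2, a venous regulator (1.73). The Notch pathway median was 0.02, with its ligand Jag1 at 1.05 and its targets Hey1 at -0.38 and Nrarp at -0.67. Precursor surface and receptor genes had a median of -0.06.

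Growth and metabolism genes of cluster 2 were lower at E11.5. S phase genes were lower in 16 of 16 members (median -0.71), G2 and M phase genes in 14 of 15 (-0.51), glycolysis genes in 16 of 16 (-0.62) and cholesterol synthesis genes in 13 of 13 (-0.52). The glucose transporter Slc2a1 had a log2 ratio of -1.58 and Dhcr7, a late enzyme of cholesterol synthesis, -1.63. The genes with the highest ratios included the calcification inhibitor Mgp (6.26, 5.57 to 7.05), Fbln5 (5.34), Ltbp3 (4.19) and the elastin gene Eln (3.98), while the extracellular matrix list had a median of 0.08 (-0.09 to 0.30) with 6 of 11 members higher. The fatty acid carrier Fabp4 (5.86) was also higher, as were Agr2 (4.69) and the heat shock genes Hspa1a (7.34, 4.83 to 12.67) and Hspa1b (3.79), members of the dissociation response list, whose median was 0.29. The genes with the lowest ratios were Vwa1 (-4.17), Clec1b (-4.01), Mogat2 (-2.40), Foxq1 (-2.40), Gsta4 (-2.01), Col26a1 (-1.89) and Clu (-1.88). The value of Vwa1 turned to 0.84 with doublets kept, and cells of this cluster were split by stage on reclustering (122 and 4 in the arterial subcluster 3, 0 and 41 in subcluster 7), and Eln and Fbln5 are among the leading genes of subcluster 7.

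Cluster 12, the other endothelial cluster (250 and 202 cells), had a median of 6064 UMIs per cell at E10.5 and 16186.5 at E11.5. Precursor surface and receptor genes had a median log2 ratio of 1.08 with 5 of 7 members higher, including the protein C receptor Procr (1.54), Cd93 (1.08) and Neurl3 (2.30). Lyve1 (2.18), Mrc1 (2.13) and Vcam1 (2.18), genes that sinusoidal endothelium shares with resident macrophages, were higher as well. The genes with the highest ratios were Fabp4 (5.23), the tip cell gene Esm1 (3.73), Sparcl1 (3.38), Tinagl1 (2.88), Ahnak (2.73), the interferon-induced Rsad2 (2.504), Gpihbp1, which anchors lipoprotein lipase on capillaries (2.45), and Rgcc (2.37). Interferon and antigen presentation genes had a median of 0.73 and dissociation response genes 0.50. S phase genes were lower in 16 of 16 members (-0.48) and cholesterol synthesis genes in 13 of 13 (-0.55), including Fdps (-1.37) from the same pathway. Rrm2 (-1.17), Mthfd2 (-1.48), Psat1 (-1.18), Mif (-1.06), Eno1 (-1.05), Rcc1 (-1.48) and Wdr77 (-1.29) were also lower. The Notch pathway median of 0.58 turned to -0.44 as a mean over cells and was 0.09 at a Leiden resolution of 0.5. On reclustering, cells of cluster 12 were also split by stage, with 93 and 3 in subcluster 4 (median 36018 UMIs at E10.5) and 6 and 94 in subcluster 5, beside the shallow vascular subcluster 2, so its ratios do not separate a change within cells from a change of subcluster.

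In hepatoblast-like cells (100 and 289 cells), the secretory and metabolic programme of the hepatocyte was higher at E11.5. All 14 measured plasma protein genes were higher (median log2 ratio 1.29), including fetuin, Ahsg (5.75), kininogen, Kng1 (3.25), complement C3 (2.18) and fibrinogen, Fga (1.88). Albumin, Alb, went from 583 CPM to 7422 CPM (3.67, 3.60 to 3.74). Hepatocyte metabolism genes were higher in 6 of 7 members (2.36), with Arg1 at -1.14. Cholesterol synthesis genes were higher in 13 of 13 members (1.30), including Hmgcs1 (1.89) and Msmo1 (1.87). Fabp1 (5.31) and the metallothioneins Mt2 (5.28) and Mt1 (4.22) were higher, and the epithelial genes Cldn6 (-4.29), Epcam (-3.98) and Wfdc2 (-3.39), which were also leading genes of nephric-like cluster 9, the imprinted Mest (-3.15) and the BMP target Id3 (-3.07) were lower. Different clusters held the class, cluster 22 at E10.5 (99 cells) and cluster 28 at E11.5 (236 cells), so genes that set these clusters apart, Alb among them, are included. Hox genes were lower in 11 of 12 measured members (-3.37), and dissociation response genes had a median of 1.53.

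Hepatic stellate or septum transversum-like cells (96 and 188 cells), the supporting cells of the liver, had higher extracellular matrix genes in 15 of 15 members at E11.5 (median 1.49), including the proteoglycans Lum (3.79) and Dcn (3.72) and the collagen Col1a1 (1.61). Col14a1 (7.49), Barx1 (5.42) and Clca3a1 (4.92) were the other genes with the largest gains, and Igdcc3 (-3.51), Hand1 (-3.04), Lmo1 (-2.94), Angpt1 (-2.70) and Gsta4 (-2.57) were lower. G2 and M phase genes were higher in 15 of 15 members (1.14).

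Smooth muscle or pericyte-like cells (700 and 380 cells) held Eln at a log2 ratio of 5.89, with Mgp (5.29), Fbn1 (2.38) and Col4a2 (1.90), while Lum (-2.29) and Dcn (-1.47) were lower. The Notch pathway was higher in 6 of 8 members (1.55), with the ligand Jag1 (2.66) and the targets Hey2 (2.04), Heyl (1.99) and Nrarp (1.81). Zcchc12 (5.75), Il13ra1 (5.50) and Col8a1 (4.47) were higher, and Hsd11b2 (-4.34), Car3 (-4.02), Igdcc3 (-3.93), Meox1 (-3.76) and Dusp9 (-2.89) lower. Cholesterol synthesis genes were lower in 13 of 13 members (-0.9996). The cells were in cluster 5 at E10.5 (692) and cluster 33 at E11.5 (364), and Eln was among the genes that set cluster 33 apart. The extracellular matrix median of 0.996 (14 of 16 members higher) was 0.32 with each library clustered alone and 0.46 with doublets kept.

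In nephric-like cells, the ducts and tubules of the early kidney, the median of all genes was 0.16 higher at E11.5. Relative to that shift, Notch pathway genes had a median of -1.43 (1 of 8 members higher before it was taken off), cholesterol synthesis genes -1.25 (13 of 13 lower), S phase genes -0.93 (16 of 16 lower), extracellular matrix genes 0.95 and dissociation response genes 1.10. Without the shift removed, Hey1 was at -2.49, Nrarp at -1.72, the signalling factor Fgf8 at -2.85, Amigo2 at -3.12 and Sfrp2 at -2.54. The ion pump subunit Fxyd2 (4.92), Dach2 (5.25), Tmem213 (5.28) and Runx1 (4.62) were higher. Runx2 went from 0 to 64.9 CPM, at least 182-fold higher. Nepn was at least 60.3-fold lower, but its ratio was 1.20 with each library clustered alone. Cluster 9 held the class at E10.5 (442 cells) and cluster 38, which was seen at E11.5 alone, held 146 of the 212 cells there.

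Gonad or adrenal-like cells (246 and 388 cells, in cluster 11 at E10.5 and clusters 35 and 36 at E11.5) had lower cholesterol synthesis genes in 13 of 13 members (-0.79) and lower S phase genes in 16 of 16 (-0.44), with dissociation response genes at 0.97. C1qtnf7 (8.80), Lgals7 (5.90), Kctd14 (5.60) and Tulp2 (5.38) were higher, and the chemokine Cxcl12 (-2.81), Igdcc3 (-2.65), Lmo1 (-1.82), Id3 (-1.78) and Phlda1 (-1.75) were lower. Genes that set these clusters apart are included, Tulp2 of cluster 36 among them. Kctd14 and Lgals7 were leading genes of cluster 37 (0 and 324 cells), whose best match was gonad or adrenal but which the naming rule left unnamed. In neural crest or glia-like cells (307 and 253 cells), extracellular matrix genes were higher in 13 of 15 members (1.07) and dissociation response genes had a median of 0.67. Also higher were Hspa1a (4.13), Kctd12 (3.72), Tagln2 (3.42), Cryab (3.31) and the endothelin receptor Ednrb (3.04). Hoxb5os (-3.92), Igdcc3 (-3.75), the retinoic acid-binding Crabp1 (-3.69), Ppp1r14a (-3.46) and Tlx3 (-3.41) were lower. Autonomic neuron-like cells (93 and 168 cells) had higher S phase genes in 16 of 16 members (1.66) and higher G2 and M phase genes in 15 of 15 (3.14), including Mki67 (3.86), Top2a (3.14), Hmmr (5.19), Kif11 (4.56) and Nusap1 (4.49). Foxq1 (5.64) and the neuropeptide Npy (4.86) were higher and Sct (-3.42), Hsd11b2 (-3.41), Arg1 (-3.09), Cck (-3.03) and Fam210b (-3.00) lower.

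**Figure D3:**
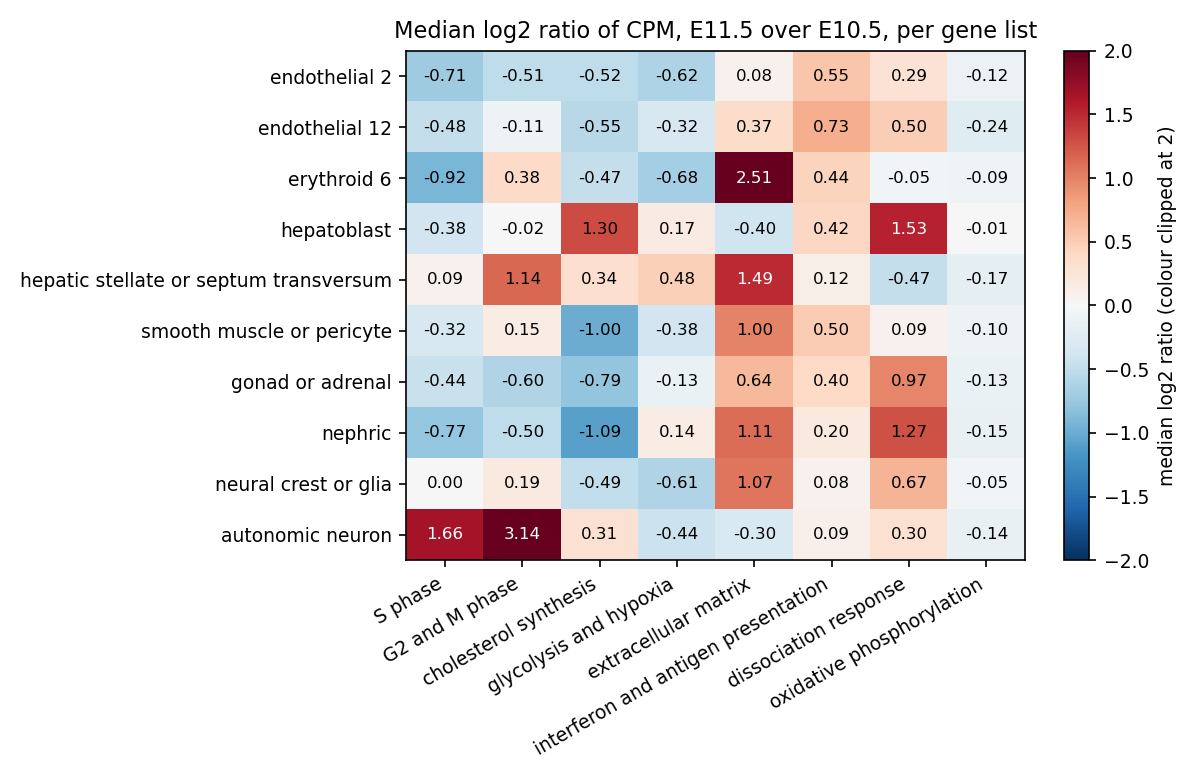
Median log2 ratio of CPM (E11.5 over E10.5) of gene lists (columns) in each compared class or cluster (lines of the grid), printed in each cell and shown by colour, which is clipped at 2, with the shift of nephric-like cells not taken off and haemoglobin UMIs left out of the total, which moves erythroid cluster 6. Cholesterol synthesis genes stood at 1.30 in hepatoblast-like and at -1.09 in nephric-like cells.

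The last comparison asked which cells held transcripts of factors that act on haematopoietic cells, among named classes of at least 50 cells, which leaves out the unnamed clusters. Kitl, the stem cell factor gene, was highest in gonad or adrenal-like cells at E10.5 (227 CPM), ahead of stellate-like (174 CPM) and hepatoblast-like cells (160 CPM). At E11.5 it was highest in hepatoblast-like cells (181 CPM, 172 to 190). Cxcl12, which retains stem cells in their niche, reached 757 CPM in sclerotome-like and 748 CPM in smooth muscle or pericyte-like cells at E10.5, and 1215 CPM in mesenchyme-like and 884 CPM in smooth muscle or pericyte-like cells at E11.5. Hepatoblast-like cells led for Dlk1 (2976 and 3734 CPM) and for the thrombopoietin gene Thpo (10.6 CPM at both stages). Bmp4 was at 146 CPM in smooth muscle or pericyte-like cells at E10.5 and at 260 CPM in mesenchyme-like cells at E11.5. Arterial endothelial-like cells led for the Notch ligands Jag1 (164 and 333 CPM) and Dll4 (153 and 139 CPM), and stellate-like cells for Csf1 (49.1 and 52.3 CPM). No UMI of Epo was counted in the ranked classes.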

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

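The tests of explanations in this part were all chosen after the results had been seen. A gene list was picked out here when its median log2 ratio was above 0 in 1 class and below 0 in another, with at least 8 measured members, counting intervals without 0 and fewer than 0.5% of random lists as extreme in both. The class furthest each way among those that met this is given. The differences themselves were not tested, since each stage had 1 library.

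Cholesterol synthesis genes had a median of 1.30 in hepatoblast-like and -1.09 in nephric-like cells. Counting intervals lay below 0 in 6 of the 10 compared classes and clusters and above 0 in 3. This cannot weigh a shift shared by all cells of a library, because the list was picked for intervals on both sides of 0. The dissociation response is argued against as a single source of both directions, because nephric-like cells had a dissociation median above 1, as hepatoblast-like cells did, with cholesterol synthesis at -1.09. For the lower values alone the dissociation response stays open. Its median was also above 0 in both compared endothelial clusters, where cholesterol synthesis genes were lower. More cycling is argued against for the gain in hepatoblast-like cells, because cell cycle genes showed no gain there. Their S phase median was -0.38 (-0.46 to -0.26), just inside the range of random lists (-0.385 to 0.171). Their G2 and M phase median was -0.02 (-0.06 to 0.17). Fewer cycling cells are argued against for the lower values of neural crest or glia-like cells, whose G2 and M phase median was 0.19 (0.10 to 0.26) and S phase median 0.00. Fewer cycling cells stay open elsewhere, since 5 of the 6 classes and clusters with lower cholesterol synthesis had lower S phase genes, but G2 and M phase genes stood at 0.15 (0.04 to 0.23) in smooth muscle or pericyte-like cells and -0.11 (-0.18 to 0.09) in endothelial cluster 12. The stage itself stays open as an untested explanation.

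The other lists that moved in opposite directions are given as values. Notch pathway genes had medians of 1.55 in smooth muscle or pericyte-like and -1.26 in nephric-like cells. S phase genes stood at 1.66 in autonomic neuron-like cells and -0.92 in erythroid cluster 6, and G2 and M phase genes at 3.14 in autonomic neuron-like and -0.60 in gonad or adrenal-like cells. BMP and TGF-β response genes stood at 0.50 in neural crest or glia-like and -0.81 in hepatoblast-like cells. Precursor transcription factors stood at 0.58 in endothelial cluster 2 and -0.91 in hepatoblast-like cells, while erythroid cluster 6, at 0.86 and percentile 99.4, did not meet the limit. The list holds Hox genes, and the Hox list had a median of -3.37 in hepatoblast-like cells, with 11 of 12 measured members lower. Glycolysis and hypoxia genes stood at 0.48 in stellate-like cells and -0.62 in endothelial cluster 2. Dissociation response genes stood at 1.53 in hepatoblast-like and -0.47 in stellate-like cells.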

How the results depend on the processing

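Of the alternatives, the joint reclustering and the Cdh5 and Runx1 count were chosen after the data had been seen, as was the set of 34 main results. Of 250 values of main results under alternatives, 207 stayed within the counting interval, 41 moved outside it and 2 reversed. Of 1038 values of 112 single genes, 843 stayed, 193 moved and 2 reversed. Results that had no value under an alternative were left out of both counts. Where no cause is given below, the cause was not tested.

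The Notch pathway median of endothelial cluster 12 reversed to -0.44 as a mean over cells, which gives shallow cells the same weight as deep ones, and was 0.094 at Leiden resolution 0.5. The haem synthesis median of erythroid cluster 6 reversed to -0.30 with CPM over all genes, where haemoglobin enters the total. Vwa1 in endothelial cluster 2 reversed to 0.84 with doublets kept, and Nepn in nephric-like cells to 1.20 with each library clustered alone.

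With a minimum of 2000 UMIs, endothelial-like shares were 3.86% at E10.5 and 2.35% at E11.5, the embryonic globin share was 93.5% in cluster 6 at E11.5 and 4.44% in cluster 31, and the hepatoblast plasma protein median was 1.15. With at most 5% mitochondrial UMIs, the erythroid-like share at E11.5 was 13.6%, the endothelial-like share at E10.5 3.91%, the cluster 31 globin share 4.44% and the smooth muscle extracellular matrix median 0.68. With doublets kept, the erythroid-like share at E11.5 was 12.3%, embryonic globin was 99.3% and 93.6% in cluster 6 and 5.88% in cluster 31, and the medians were 0.73 for precursor transcription factors and -0.78 for cholesterol synthesis in endothelial cluster 2 and 0.46 for extracellular matrix in smooth muscle. With each library clustered alone, haemogenic-like cells numbered 17 and 0 (0% of cells and 0% of blood cells at E11.5), the hepatoblast-like share at E10.5 was 0.999%, endothelial-like shares were 3.51% and 2.12%, cluster 6 globin at E11.5 was 94.0%, and the medians were 0.70 for precursor transcription factors, 1.16 for plasma proteins and 0.32 for extracellular matrix. With the reported genes kept in the clustering, the hepatoblast-like share at E10.5 was 0.986%, cluster 6 globin at E11.5 was 93.9%, and the medians were 1.15 for plasma proteins and 0.64 for extracellular matrix. The endothelial-like share at E11.5 was 2.52% at resolution 0.5. At resolution 2.0, the extracellular matrix median was 0.64 and Cxcl12 in smooth muscle at E10.5 was 800.2 CPM. As medians over cells, globin shares were 99.6% and 94.0% in cluster 6 and 1.42% in cluster 31. As means over cells, the hepatoblast medians were 1.48 for plasma proteins and 1.01 for cholesterol synthesis. With CPM over all genes, the red cell membrane median was 0.44 and Cxcl12 in smooth muscle 716 and 846 CPM.

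No haemogenic-like class was found with a minimum of 2000 UMIs, with at most 5% mitochondrial UMIs or with joint reclustering, so its shares and levels have no value there. List medians of endothelial cluster 2 had no value at resolution 0.5 or with at most 5% mitochondrial UMIs, nor had globin of erythroid cluster 31 at resolution 0.5. The number of cells limits the levels of the haemogenic-like group: 6 cells at E11.5 leave Hlf between 29.0 and 104 CPM.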

Other observations

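The tests of explanations in this part were all chosen after the results had been seen.

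Macrophage-like cells fell into 3 subclusters that were split by stage, with 24 and 12 cells in subcluster 2, 1 and 27 in subcluster 5 and 2 and 57 in subcluster 7. Germ cell-like cells numbered 14 at E10.5 and 41 at E11.5, and neuron-like cells 77 and 32. In arterial endothelial-like cells, Sox17, an arterial regulator, was held at 393 and 458 CPM, Hey2 at 90.3 and 141 CPM, Gata2 at 70.8 and 115 CPM, and the gap junction gene Gja5 at 843 and 531 CPM. Neural crest or glia-like cells had lower cholesterol synthesis genes in 13 of 13 members (-0.49) and lower glycolysis genes in 15 of 17 (-0.61).

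Among cells with at least 5000 UMIs, transcripts of Y-linked genes without Xist were counted in 81.6% at E10.5 and 89.3% at E11.5. Xist without a Y-linked gene was counted in 1 cell at E10.5 and 0 at E11.5, and neither was counted in 1170 and 803 cells.

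Haemogenic-like cells held endothelial Cdh5 and blood genes together. At E10.5, 5 of 20 precursor transcription factors stood above all 24 other clusters of at least 20 cells, which no mixture of those clusters gives. This argues against doublets within those clusters as the whole source. Doublets with a blood progenitor were not tested, since the unnamed blood cluster B3, with 8 cells at E10.5, was under that size. In the haemogenic-like cells at E10.5, Cdh5 stood at 203 CPM (169 to 242). Its upper bound was 7.32 CPM in the other 2 blood clusters of at least 20 cells, macrophage-like subcluster 2 and erythroid cluster 6. Cdh5 was a naming marker of the group and was not kept out of the clustering, so a high level was favoured in advance. This comparison therefore cannot weigh free endothelial RNA. Single doublets among the haemogenic-like cells stay open, since with doublets kept 12.5% and 28.6% of the group were marked (2 of 16 and 2 of 7 cells), against 7.995% of all cells in both libraries. The median doublet score of the group as analysed was 0.141 at E10.5 and 0.122 at E11.5. In all cells it was 0.067 and 0.053, and the lowest scores removed were 0.185 and 0.164. A transition from endothelium to blood may underlie the mixed profile, a hypothesis found and examined in the same 15 and 6 cells.

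Erythroid-like clusters 24 and 31, rich in adult globin at E11.5, were almost limited to that library, and the 8 cells of cluster 24 at E10.5 had 8.26% adult β-like globin. Less liver in the E10.5 library as the sole cause is argued against, because their number per hepatoblast-like and stellate-like cell was 42.0-fold higher at E11.5 (21.2 to 97.6), from 8 cells beside 196 and 818 beside 477. Adult globin from free RNA is argued against for cluster 24, because 79.9% of its β-like globin was adult, and the highest upper bound among neural crest, nephric and smooth muscle-like cells was 44.6%. The onset of definitive red cell formation in the liver between the stages may account for the clusters, a hypothesis that 1 library per stage leaves untested.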
